A study of Mus musculus with 5 samples.

How the data were processed

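Polyadenylated RNA of mouse ES cells was sequenced in 5 libraries, per the labels' protocols: 3 of iTDPKO cells, whose floxed Tardbp allele loses exon 3 under Cre, and 2 of cTDP cells, whose allele is wild type. RNA was captured on oligo-dT beads and made into cDNA by an Illumina protocol, per the labels. The labels name no step that marks strand, so reads of a gene and of a gene antisense to it were not separated. Machine, run and lane fields in the reads show 1 run of 1 machine and a separate lane for each library.

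The deposited files hold 1 line per placed read of 40 bases, with its sequence, its position on the mm9 genome or on a set of splice junctions named by gene, and an alignment score. That score, deposited by the authors for each read, was used only for an alternative that kept reads scoring at least 100. The aligner, its settings and the reads left out before deposit are not given in the sources used here. The deposited positions name no gene outside the junctions and are in mm9, and the annotation used was GENCODE M21 in GRCm38. Positions were therefore never carried between builds: genes and exons came from matching the read sequences again, in GRCm38, and introns and junctions from the authors' positions, in mm9.

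Read sequences were aligned to the GENCODE M21 transcripts, without retained-intron and readthrough transcripts, with BWA 0.7.19 mem (seeds of 15 bases, minimum score 20) and a program compiled with g++ 11.4.0. A read was counted for a gene when its best alignments, with at most 10 clipped bases and a score of at least 28, lay on 1 gene alone, and reads that fitted more than 1 gene equally well were left out (2.48% to 2.55% of reads). Between 85.5% and 93.3% of reads were counted, and 4.17% to 12.0% matched no transcript. The share of each gene's 31-base words found in another gene was computed, since copies can take or give reads. Repeated starts were common: 30.6% to 52.6% of reads had the start and strand of another read of their library. Without molecular identifiers these can be amplified copies or separate molecules, so they were kept, and counted once in an alternative.

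Genes with at least 1 CPM in at least 2 libraries and at least 20 reads in all were tested. Read counts made here were scaled by trimmed mean of M-values factors (30% of log ratios and 5% of abundances trimmed, own code) and tested with limma-voom (limma 3.58.1, R 4.3.3), iTDPKO minus cTDP over all 5 libraries with no covariate. CPM, the usual unit of sequencing depth, are relative to all reads on the tested genes after this scaling. The design fixed before the data were examined used a count-model test where the deposited columns were counts. They are positions and scores, so its stated fallback, limma-voom, was used. P-values were adjusted by Benjamini and Hochberg's method, with a threshold of 0.05. Lists of 618 genes were fixed before the data were examined, as were the tests, the threshold, the alternatives and the rule for named genes, except where stated. Of the listed genes 617 matched a symbol and 492 were measured. Lists with at least 3 measured genes were tested with camera at a correlation of 0.01, then with an estimated correlation, and with fry. At the estimated correlation 0 of the 33 lists passed, against 2 with the preset one, and fry passed 4 lists one way and 13 in either direction. The lists of blood and endothelial, 2-cell-like and X-inactivation genes had fewer than 3 measured genes and were not tested.

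Named genes followed a rule: Tardbp and Tbc1d1, then the 10 largest log2 fold changes in each direction among genes that passed, had groups that did not overlap and a mean of at least 5 CPM, leaving out unnamed genes, pseudogenes and genes sharing 50% or more of their sequence with copies. Up to 4 genes with the smallest p were taken from each list. After the values were seen, list members were narrowed to those that passed over all genes. For exons and introns the 5 genes with the smallest adjusted p were named.

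Exon use was tested with limma's voom and diffSplice on exon segments (GRCm38) with at least 20 reads, each against the other segments of its gene. Intronic segments were bins of 200 bases (mm9) inside introns of the authors' junctions, at least 40 bases from any junction. Those with at least 10 reads were tested. The exonic reads of the gene were added as a further segment. Each intronic segment was tested against the weighted mean of that segment and the gene's other tested intronic segments. No mm9 annotation was used here. Instead, only reads that matched no GENCODE M21 transcript were counted in introns. Segments where reads that matched a transcript outnumbered them were dropped. Retained-intron and readthrough transcripts were not among those matched, so exons annotated in them alone are not excluded. On simulated data the exon test with limma's default span of 0.5 for the mean-variance trend made many false calls among very abundant segments, so a span of 0.1 was used for exons and junctions. That choice was made after the data were seen. The intronic test made few false calls on simulated data and kept the default span. Spearman's rho of log2 fold change with total intron length (GRCm38) used 5 expression bins. The share of Tardbp reads in exon 3 has exact binomial 95% intervals, a limit of 3 counts where no read was seen, and an exact permutation test.

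Each step was tested on simulated data. Counts of genes and segments were drawn independently from a negative binomial distribution with 1 dispersion, 0.0039, the median over 7311 genes. They held no repeated starts, no excess on chromosome 6 and no correlation between genes. The shares of false calls below therefore hold for that setting and can be too low for the real libraries. With 13118 genes and the real library sizes, 56.1% of genes changed 1.5-fold, 84.6% of those changed 2-fold and 95.4% of those changed 4-fold were called, and 1.28% of calls were unchanged genes. All 5 changed lists and 0 of 25 unchanged lists were called. Of exon segments, 30% of those changed 2-fold and 79% of those changed 4-fold among 108630 were called, and 6.30% of calls lay in genes with no changed segment. Of intronic segments, 38% of those changed 4-fold and 100% of those changed 16-fold among 7989 were called, and 4.17% of calls lay in genes with no changed segment. Of 50000 reads drawn from the transcripts with errors at 1% of bases, 92.5% were placed on their own gene and 0.052% on another.

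No 2 libraries agreed within sampling noise: the chi-square per gene lay between 2.86 and 17.0. Alternatives were median-of-ratios or total-count scaling, no filter or at least 5 CPM, limma-trend on log2(CPM + 1), sample quality weights, the replicate number as a block, a GC correction, thinning, repeated starts counted once, the score minimum, other segment sizes and minimums, and each library left out in turn. Chosen after the data were seen were junction reads only, leaving out iTDPKO replicate 3 and cTDP replicate 2 together, leaving out chromosome 6, and the spans. Tables and figures used GenomicRanges 1.54.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.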

Results

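Poly(A) RNA of mouse embryonic stem (ES) cells was sequenced as 40-base reads in 5 libraries, 3 from iTDPKO cells and 2 from cTDP cells. In both kinds of cell, 1 allele of Tardbp had been exchanged for a transgene in which the CAG promoter drives ErCreEr, a Cre recombinase that enters the nucleus when tamoxifen is bound. The other allele had loxP sites around exon 3 in iTDPKO cells and was wild type in cTDP cells. Cells of both kinds received 4-hydroxytamoxifen at 100 ng/ml for 72 h, so that exon 3 could be removed in iTDPKO cells alone. The strain was C57BL/6, the passage was between 12 and 15, and the medium held leukaemia inhibitory factor with inhibitors of GSK3 and MEK, which keep mouse ES cells in the naive state.

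The deposited files held 11318401, 11068592 and 4298954 placed reads for iTDPKO replicates 1, 2 and 3, and 10214424 and 2240687 for cTDP replicates 1 and 2. Of these, 10557158, 10262506, 3675372, 9515674 and 1931746 were placed on genes, in the same order. The shallowest libraries, iTDPKO replicate 3 and cTDP replicate 2, had uncalled bases in 32.3% and 45.8% of their reads, against 2.41% to 5.13% in the others. Pearson's r of log2 CPM (read counts scaled to a common library size) between pairs of libraries ran from 0.961 to 0.989 across genes, which are not independent replicates. The iTDPKO replicate 2 library stood apart on chromosome 6, where its 411 genes of at least 10 CPM had a median log2 difference of 0.30 from the mean of the other libraries, or 23.4% more RNA. The medians of its other chromosomes lay between -0.03 and 0.04. The groups differ in ES cell line as well as in the Tardbp allele, and nothing in the labels says whether replicates were separate cultures. The p-values therefore measure the spread between these samples, which may be technical, and cannot separate the deletion from a difference between lines.

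**Figure D1:**
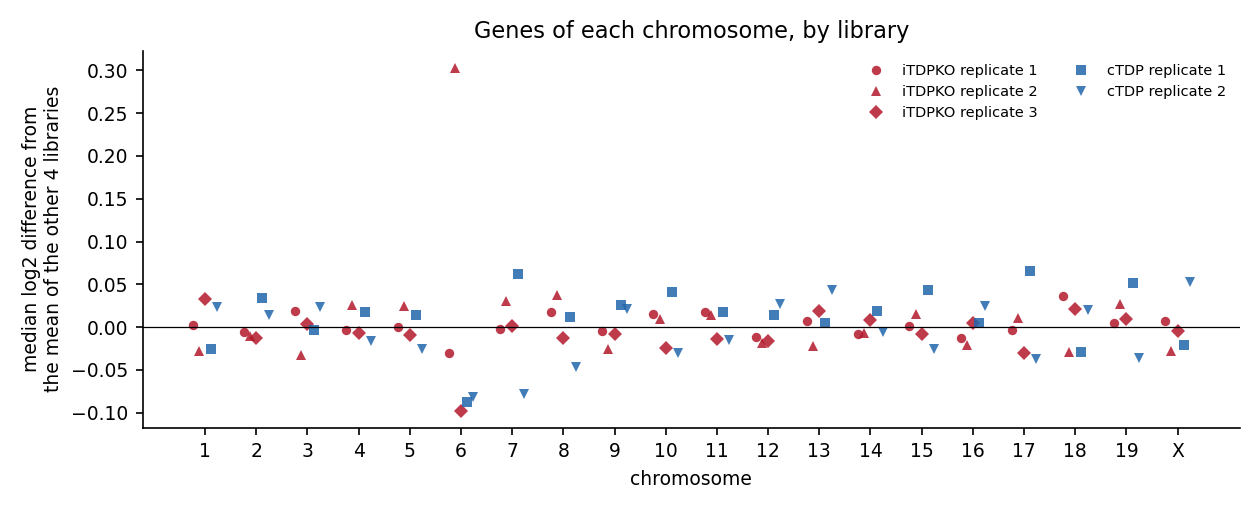
Median log2 difference of each library from the mean of the other libraries (vertical axis), over the genes of each chromosome (horizontal axis). Chromosome 6 of iTDPKO replicate 2 lies at 0.30, while its other chromosomes lie between -0.03 and 0.04.

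The comparison of iTDPKO with cTDP asks how RNA in ES cells changes when Tardbp is deleted. Tardbp encodes TDP-43, an RNA-binding protein that regulates splicing, and it was measured first in every library. Tardbp RNA (GRCm38, chromosome 4, 148612382 to 148627019) fell to 34.4 ± 2.09 CPM (SD, n = 3) in iTDPKO from 190 ± 19.5 CPM (SD, n = 2) in cTDP. The log2 fold change was -2.46 (SE 0.11, limma adjusted p 2.4e-07). In exon 3 (148621949 to 148622112, 164 bases), the 3 iTDPKO libraries had 0 of 362, 0 of 331 and 0 of 136 Tardbp reads, which allows shares of up to 0.829%, 0.906% and 2.21% by a limit of 3 counts. Exact binomial 95% intervals for the same libraries reach 1.01%, 1.11% and 2.68%. Exon 3 held 41 of 1640 Tardbp reads in cTDP replicate 1, or 2.50% (exact binomial 95% interval 1.80% to 3.38%), and 10 of 395 in cTDP replicate 2, or 2.53% (1.22% to 4.61%). These intervals and limits cover counting error only. The mean share differed by -2.52 percentage points with an exact two-sided permutation p of 0.1, the smallest that the 10 splits of 5 libraries allow.

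Tardbp reads remained outside exon 3 in iTDPKO, though each of the other 5 exons had fewer relative to the depth of each library. Exon 2 had 25, 30 and 7 reads in the iTDPKO libraries and 129 and 30 in the cTDP libraries, exon 4 had 4, 3 and 0 against 22 and 11, and exon 6, which holds most of the 3' untranslated region, had 314, 290 and 122 against 1400 and 326. On the authors' splice junctions (mm9), the junction between exons 1 and 2 had 3, 11 and 1 reads in iTDPKO and 4 and 3 in cTDP, too few to compare. The junction into exon 3 had 0 reads in each iTDPKO library and 5 and 4 in the cTDP libraries, and the junction out of it had 0 in each and 6 and 2. Later junctions were nearly as empty in iTDPKO. Between exons 4 and 5 there were 0, 1 and 0 reads against 13 and 2, and between exons 5 and 6, 1, 1 and 0 against 8 and 1. Junction reads alone therefore do not set exon 3 apart. Copies elsewhere in the transcriptome shared 26.3% of the 31-base words of Tardbp, and other genes overlapped 23.4% of its exonic bases. Reads from those sources cannot be separated fully from Tardbp's own.

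Tbc1d1, a Rab GTPase-activating protein in the traffic of glucose transporters and the gene that the series' title names, had the second-largest fall among the named genes. Tbc1d1 RNA (GRCm38, chromosome 5, 64156305 to 64351486) fell to 13.1 ± 0.815 CPM (SD, n = 3) from 96.2 ± 1.13 CPM (SD, n = 2), a log2 fold change of -2.88 (SE 0.13, limma adjusted p 2.4e-07). Every iTDPKO library lay below both cTDP libraries. Reads on the splice junctions that the authors assigned to Tbc1d1 numbered 28, 20 and 5 in iTDPKO and 153 and 41 in cTDP. None of its 31-base words occurred in another gene.

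**Figure D2:**
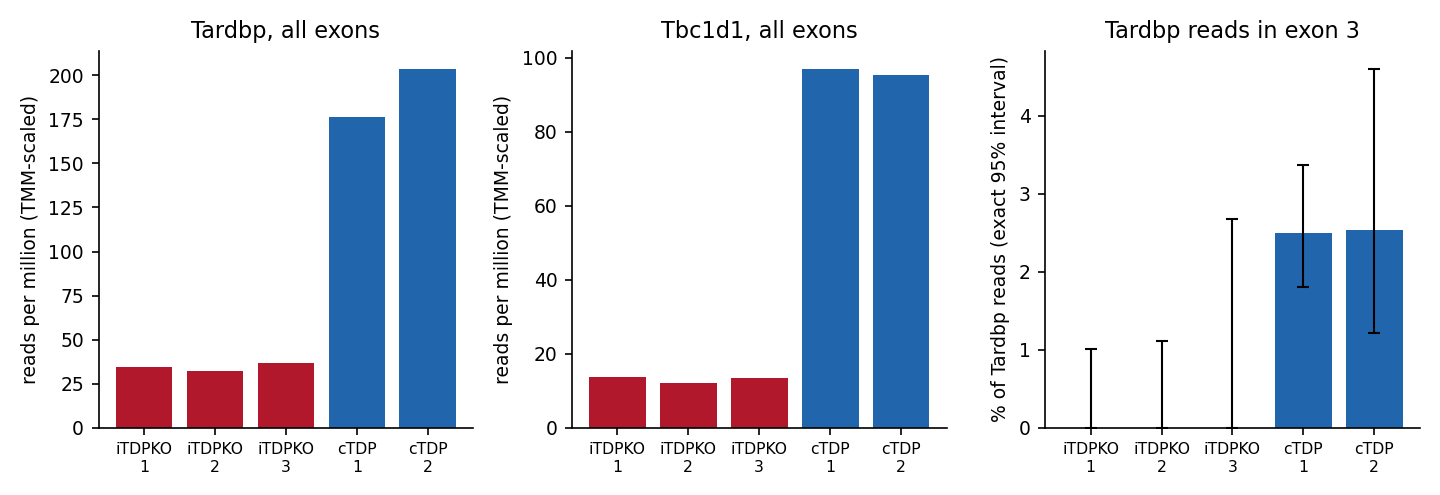
CPM of Tardbp and of Tbc1d1 and the percentage of Tardbp reads that lie in exon 3 (vertical axes) in each library (bars), the last with exact 95% intervals of counting error. All 3 iTDPKO libraries lie below both cTDP libraries in each, and their share of exon 3 reads is 0.

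More genes passed as lower than as higher in iTDPKO. Med27, a subunit of the Mediator complex, Rfc2, a subunit of the clamp loader in DNA replication, and Usp15, a deubiquitinase, fell further than Tardbp. Inpp5f, an inositol phosphatase, and Lsm5, a subunit of the ring that binds the end of U6 and of decaying mRNA, rose the most. Of 13380 genes tested with limma-voom, 357 passed at an adjusted p under 0.05, 285 lower and 72 higher in iTDPKO, and 1330 lower and 961 higher had an unadjusted p under 0.05. The unadjusted counts were nearly even with total-count scaling (1193 lower, 1151 higher) and with limma-trend (1176 lower, 1133 higher), where 248 and 232 of the genes that passed were lower and 92 and 91 higher. All 357 had groups that did not overlap, as did 35.1% of all genes tested, where chance gives 20%. The change reached 1 on the log2 scale in 91 of the lower and 25 of the higher genes. The count rested on the cTDP libraries: 30 genes passed without cTDP replicate 1, all lower, and 106 passed without cTDP replicate 2, 96 of them lower. It was 211 without both libraries with many uncalled bases, 187 with all libraries thinned to the depth of the shallowest, and 72 with reads of 1 start and strand counted once.

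The 10 largest falls included Tardbp and Tbc1d1. Med27 (chromosome 2) fell to 5.15 ± 1.65 CPM (SD, n = 3) from 37.9 ± 2.63 CPM (SD, n = 2), a log2 fold change of -2.98 (SE 0.23, adjusted p 1.3e-05). Rfc2 (chromosome 5, 134581366 to 134601805) fell to 20.02 ± 2.10 CPM from 135 ± 1.36 CPM (log2 -2.80, SE 0.12, adjusted p 2.4e-07). Usp15 (chromosome 10) fell to 13.9 ± 1.32 CPM from 80.0 ± 1.48 CPM (log2 -2.51, SE 0.14, adjusted p 8.6e-07). Ascc1, part of a transcriptional coactivator complex, fell by 2.40 on the log2 scale, and Rec8, the meiotic cohesin subunit, fell by 2.29. Ptcd2, a mitochondrial RNA-binding protein, fell by 2.15, Atraid, a gene induced by retinoic acid, by 2.27, and Asb13, a substrate adaptor of ubiquitin ligases, by 2.11. Without cTDP replicate 1, Atraid (adjusted p 0.0669) and Asb13 (adjusted p 0.148) missed the threshold, while the other 6 of the 8 falls besides Tardbp and Tbc1d1 passed.

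The 10 largest rises were led by Inpp5f, which rose to 8.42 ± 3.19 CPM (SD, n = 3) from 0.946 ± 0.122 CPM (SD, n = 2), a log2 fold change of 2.90 (SE 0.60, adjusted p 0.0261). Lsm5 rose by 2.83 (SE 0.44, adjusted p 0.00501) and Rpa3, the smallest subunit of the single-strand DNA-binding protein RPA, by 1.68 (SE 0.36, adjusted p 0.0324). Both lie on chromosome 6 and were highest in iTDPKO replicate 2, though all 10 rises also passed without that library. Copies elsewhere shared 44.7% of Lsm5's sequence. The rest were Selenoi (2.06), an enzyme of phosphatidylethanolamine synthesis, Tcfl5 (1.67) and Klf12 (1.54), which are transcription factors, Prelid3a (1.46), a lipid transfer protein, Ndufab1 (1.44), the mitochondrial acyl carrier protein, Cnga3 (1.41), a cyclic nucleotide-gated channel, and mt-Cytb (1.40), the mitochondrially encoded subunit of complex III. Without cTDP replicate 1 none of the 10 passed in limma-voom, where the highest adjusted p was 0.732 and the log2 fold changes were 0.75 to 2.63. That fit gave 486 higher genes at an unadjusted p under 0.05. Without cTDP replicate 2 only Prelid3a and Ndufab1 passed and the highest adjusted p was 0.147, while Klf12 and Cnga3 missed the threshold without iTDPKO replicate 1 (adjusted p 0.0547 and 0.0538) and Selenoi without iTDPKO replicate 3 (0.0519). With reads of 1 start and strand counted once only Inpp5f, Tcfl5 and Prelid3a passed, and the log2 fold changes of Lsm5 (0.46), Rpa3 (0.55), Ndufab1 (0.62) and mt-Cytb (0.68) were much smaller. Selenoi (1.96), Klf12 (1.65) and Cnga3 (1.41) missed the threshold there at log2 fold changes close to those with all reads. Ndufab1 also had 0.56 (adjusted p 0.349) at an alignment score of at least 100, and Rpa3 had 0.07 on junction reads alone.

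**Figure D3:**
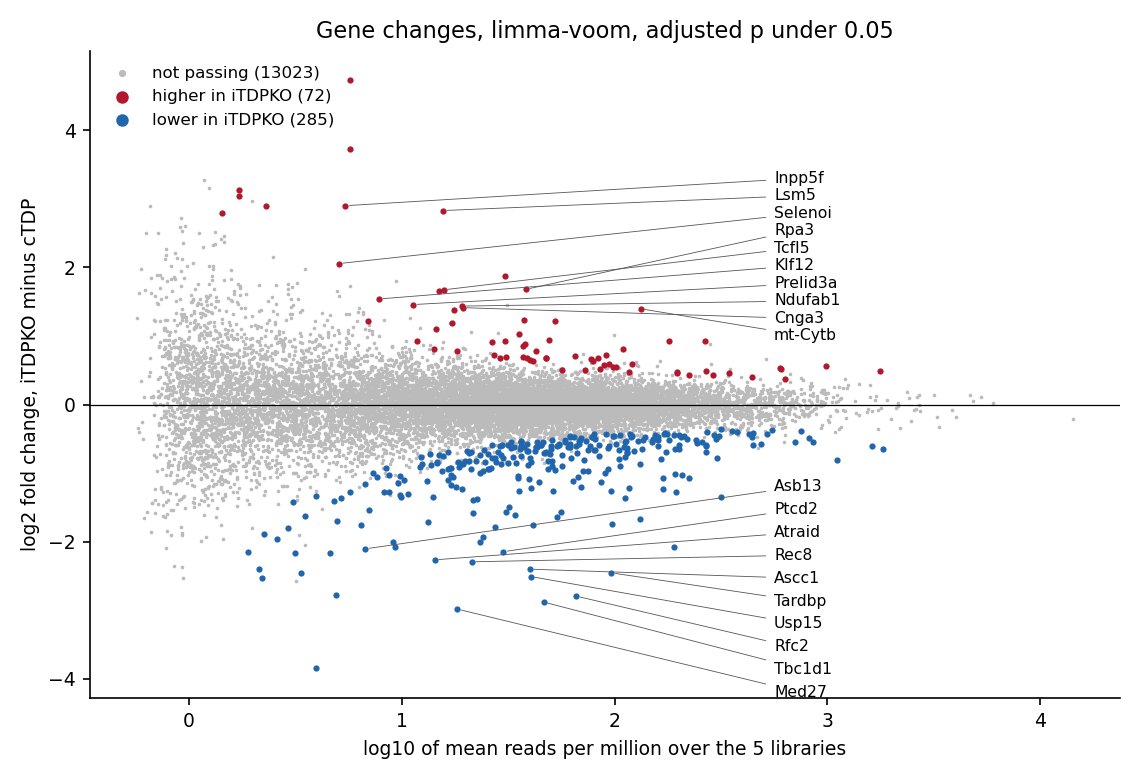
Log2 fold change of each tested gene, iTDPKO minus cTDP (vertical axis), against log10 of its mean CPM (horizontal axis). The 72 genes that rose and the 285 that fell are coloured, and the genes with the largest changes under the rule for named genes are labelled.

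Among genes tied to TDP-43 in earlier work, falls outnumbered rises, as they did among all genes that passed (285 lower, 72 higher). Of 15 measured genes reported to hold cryptic exons that TDP-43 represses, 3 fell: Usp15, Tecpr1, which tethers autophagosomes, with a log2 fold change of -2.01 (SE 0.15), and Mib1, a ubiquitin ligase of Notch signalling, with -1.58 (SE 0.18). None of the 15 rose in limma-voom or limma-trend, where 3 were higher at an unadjusted p under 0.05, and 3 rose and 6 fell when adjusted over the list alone. Of 15 other genes reported as targets, Tbc1d1 and Atg7, an autophagy enzyme (log2 -1.14, SE 0.20), fell and Grn, which encodes progranulin (log2 0.54, SE 0.09), rose, against 1 risen and 3 fallen adjusted over the list alone. The camera test of each list against other genes gave adjusted p of 0.221 and 0.223, and fry, which asks whether the genes move on balance one way, gave 0.0405 and 0.0172. With reads of 1 start and strand counted once both lists passed camera (0.0389 and 0.0449), and with no filter the cryptic exon list did (0.0437), while with other scalings or filters, thinning or left-out libraries the highest values were 0.274 and 0.375. Both lists had an adjusted p of 0.784 with an estimated correlation. The medians were -0.11 and -0.07, above the means of -0.40 and -0.28. Part of both lists came from published work on Tardbp-deleted ES cells, so they are not independent evidence of a direction. Atg7 had an adjusted p of 0.385 without cTDP replicate 1 and 0.0545 without cTDP replicate 2, and Grn had 0.213 and 0.126. Grn had a log2 fold change of 0.10 (adjusted p 0.882) with reads of 1 start and strand counted once. The calls of Tecpr1 and Mib1 held without each library in turn.

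Genes of amyotrophic lateral sclerosis and frontotemporal dementia moved both ways. Of 21 measured, Grn and Vcp, a protein-unfolding ATPase (log2 0.55, SE 0.12), rose, and Atxn2, an RNA-binding protein of stress granules (-0.67, SE 0.10), and Mapt, which encodes tau (-0.46, SE 0.10), fell. Adjusted over the list alone, 3 rose and 2 fell, and camera gave an adjusted p of 0.578. Of 18 SR proteins and related splicing factors, U2af1, which recognises the 3' splice site (-0.83, SE 0.18), and Nono, a paraspeckle protein (-0.39, SE 0.09), fell, and 4 fell adjusted over the list alone. In limma-trend none of the 18 passed. Of 28 hnRNP and related RNA-binding genes, Celf1, a regulator of splicing and mRNA decay (0.44, SE 0.10), rose, also alone when adjusted over the list alone. Copies elsewhere shared 68.1% of Vcp's and 63.7% of U2af1's sequence. Without cTDP replicate 1 Vcp, Atxn2, Mapt, U2af1, Nono and Celf1 missed the threshold (adjusted p 0.293 to 0.484), and without cTDP replicate 2 all but Atxn2 did (0.149 to 0.209). Without iTDPKO replicate 1, Mapt (0.0575), Vcp (0.0598), Celf1 (0.103) and Nono (0.0702) missed it. Without iTDPKO replicate 2, Mapt (0.0533), Vcp (0.0501), Celf1 (0.0593), U2af1 (0.0593) and Nono (0.0780) missed it, and without iTDPKO replicate 3 Mapt did (0.0509). With reads of 1 start and strand counted once none of these 6 passed (0.121 to 0.744), and the log2 fold changes were -0.23 for U2af1, 0.20 for Vcp and 0.17 for Celf1, against -0.55 for Atxn2, -0.38 for Mapt and -0.41 for Nono. At an alignment score of at least 100 U2af1 had -0.12 (adjusted p 0.896) and Nono -0.81 (0.435). The hnRNP list passed camera without iTDPKO replicate 3 (0.0127), without both libraries with many uncalled bases (0.0387) and with no filter (0.00269), and had 0.925 with an estimated correlation. With reads of 1 start and strand counted once its direction turned to lower (0.0969).

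Tbc1d1 was the exception among genes of glucose and body weight. It was the only gene to pass among 27 of glucose uptake and insulin signalling and among 10 that human genetics ties to body weight, over all genes and adjusted over the list alone. The medians of these lists were 0.04 and 0.01, and camera gave adjusted p of 0.966 and 0.229. The body weight list, whose mean was -0.36, passed fry (adjusted p 0.0267) and had 0.784 in camera with an estimated correlation. Of 24 genes of lipid synthesis and storage, 1 fell, Scd1, a fatty acid desaturase (-0.43, SE 0.10), also the count adjusted over the list alone. Of 22 genes of glycolysis and hypoxia, Eno1, a glycolytic enzyme (0.93, SE 0.19), rose, and 2 rose and 5 fell adjusted over the list alone. Copies shared 77.5% of Eno1's sequence, and its log2 fold change was -0.17 with reads of 1 start and strand counted once. With those reads counted once Scd1 had a log2 fold change of -0.41 and an adjusted p of 0.576. Scd1 and Eno1 had adjusted p of 0.346 and 0.262 without cTDP replicate 1 and 0.318 and 0.215 without cTDP replicate 2. Scd1 also missed the threshold without iTDPKO replicates 2 (0.0756) and 3 (0.0650), and Eno1 without iTDPKO replicate 1 (0.0572).

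Mitochondrially encoded and imprinted genes were the lists that passed camera at the preset correlation, and neither passed with an estimated one. Of 7 mitochondrially encoded genes measured, mt-Cytb and mt-Nd4, a subunit of complex I (log2 1.22, SE 0.26), rose, and 4 rose adjusted over the list alone. The camera test gave an adjusted p of 0.0128, and an adjusted p = 0.823 with an estimated correlation. The other 5 did not pass, among them mt-Nd2, with 118 ± 36.7 CPM in iTDPKO and 69.8 ± 29.0 CPM in cTDP, and mt-Nd6, with 53.5 ± 14.7 and 74.4 ± 47.2 CPM. Of 20 imprinted genes, Phlda2, a growth regulator of the placenta (0.67, SE 0.12), rose, and 5 rose adjusted over the list alone, with an adjusted p of 0.0128 that became adjusted p = 0.784 with an estimated correlation. Copies elsewhere shared 62.96% of mt-Nd4's sequence. Of all reads, 0.128%, 0.106% and 0.0704% lay on the mitochondrial chromosome in iTDPKO and 0.0571% and 0.0951% in cTDP, so the groups overlapped. Mest, on chromosome 6, had 28.4, 72.3 and 27.1 CPM in iTDPKO replicates 1, 2 and 3. The mitochondrial list gave an adjusted p of 0.968 and the imprinted list 0.237 without cTDP replicate 1, and the mitochondrial list gave 0.0669 without iTDPKO replicate 1, 0.0514 after a GC correction, 0.0866 with libraries thinned to equal depth and 0.0604 with reads of 1 start and strand counted once. Phlda2 and mt-Nd4 had adjusted p of 0.258 and 0.623 without cTDP replicate 1 and of 0.0923 and 0.126 without cTDP replicate 2, and mt-Nd4 had 0.0633 without iTDPKO replicate 1. Counting reads of 1 start and strand once, Phlda2 had a log2 fold change of 0.38 (adjusted p 0.471) and mt-Nd4 of 0.70 (0.281).

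Markers of the naive state showed no change that passed. Of 24 naive pluripotency genes none passed in limma-voom, 3 were higher and 3 lower at an unadjusted p under 0.05, and 1, Dppa5a, rose adjusted over the list alone. Pou5f1, the central pluripotency factor, had 1144 ± 50.03 CPM in iTDPKO and 1096 ± 104 CPM in cTDP, and Nanog had 688 ± 29.4 and 698 ± 32.6 CPM. Of 8 neural progenitor genes 1 fell, Ncam1, a cell adhesion molecule (-0.77, SE 0.17), while 2 rose and 1 fell adjusted over the list alone. Of 9 primitive endoderm genes 1 fell, Lamb1, a laminin chain (-0.71, SE 0.15), and 2 adjusted over the list alone. Of 16 chaperones of the endoplasmic reticulum, Calr (-0.61, SE 0.09) and Hsp90b1 (-0.54, SE 0.10) fell, 3 fell adjusted over the list alone, and camera gave an adjusted p of 0.0558. Of 12 heat shock genes 1 rose, the co-chaperone Bag3 (0.78, SE 0.18), and 1 rose and 3 fell adjusted over the list alone. Of 18 autophagy and lysosome genes, Atg7 alone passed, also adjusted over the list alone. Without cTDP replicate 1 each of Ncam1, Lamb1, Calr, Hsp90b1 and Bag3 missed the threshold (adjusted p 0.268, 0.544, 0.230, 0.302 and 0.688), and without cTDP replicate 2 each did but Lamb1 (0.191, 0.0630, 0.141 and 0.120). None of the 5 passed with reads of 1 start and strand counted once (0.109 to 0.538), though the log2 fold changes of Ncam1 (-0.74), Calr (-0.59), Hsp90b1 (-0.53) and Bag3 (0.74) stayed close and that of Lamb1 was -0.48. The chaperone list passed camera without iTDPKO replicate 3 (0.0170), with at least 5 CPM (0.0360) and with no filter (0.00403), and had 0.784 with an estimated correlation. Bag3 missed it without iTDPKO replicates 1 (0.0990) and 2 (0.0517), and Ncam1 without iTDPKO replicate 2 (0.0536).

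In 17 of the 33 tested lists, with 232 memberships, no gene passed in limma-voom or limma-trend. Adjusted over the list alone 2 rose and 1 fell in them, and at an unadjusted p under 0.05 they held 26 higher and 22 lower. They were naive pluripotency, primed epiblast (11 measured), mesoderm and primitive streak (4), trophoblast (6), fibroblast feeder (7), p53 targets (19), apoptosis (14), cell cycle genes of G1 and S phase (24) and of G2 and M phase (20), fatty acid oxidation (23), cholesterol synthesis (20), nuclear genes of oxidative phosphorylation (19), the integrated stress response (18), the interferon response (6), immediate early genes (11), replication histones (3) and Y-linked genes (3). Their medians ran from -0.23 for replication histones to 0.32 for the interferon response, which passed fry (adjusted p 0.0267) but not camera (0.0558). That list passed camera without iTDPKO replicate 3 (0.0386), without both libraries with many uncalled bases (0.0387) and with no filter (0.00269), and had an adjusted p of 0.784 with an estimated correlation. With no filter, cholesterol synthesis (adjusted p 0.0138) and immediate early genes (0.0399) also passed camera. In either direction, fry passed cholesterol synthesis (adjusted p 0.0282), apoptosis (0.000434) and cell cycle genes of G2 and M phase (0.00906). Of 2 measured markers of blood and endothelium, both fell: Cd68, a lysosomal glycoprotein (-0.83, SE 0.11), and Pecam1, a cell adhesion molecule that mouse ES cells also express (-0.56, SE 0.11). Both counts were the same adjusted over the list alone. Cd68 had an adjusted p of 0.199 without cTDP replicate 1, and Pecam1 had 0.200 without cTDP replicate 1 and 0.179 without cTDP replicate 2. Both missed the threshold with reads of 1 start and strand counted once (-0.68, adjusted p 0.0721, and -0.55, adjusted p 0.311). The lists of 2-cell-like and X-inactivation genes had 1 measured gene each, Eif1a (199 ± 8.38 against 201 ± 18.7 CPM) and Rlim, which rose adjusted over its list alone (26.5 ± 4.37 against 16.6 ± 0.564 CPM).

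Exon use differed in Kazn, Hsp90ab1, Mcm10, U2af2 and Synj2bp, the 5 genes with the smallest adjusted p. In Synj2bp, which encodes a mitochondrial outer membrane protein, use of the last exon of 2 of its 4 transcripts fell (GRCm38, chromosome 12, 81499142 to 81502166), with 15, 25 and 11 reads in iTDPKO against 163 and 40 in cTDP and a log2 difference from the gene's other segments of -4.83 (SE 0.31). In Kazn, a desmosome-associated protein, use of the last exon of 1 of its 7 transcripts fell (chromosome 4, 142102390 to 142104954), with 14, 19 and 5 reads against 231 and 59 (-4.08, SE 0.27, adjusted p 1.9e-17). In U2af2, the partner of U2af1 in recognising the 3' splice site, a segment of the 3' untranslated region fell (chromosome 7, 5079584 to 5079932, log2 -2.21, SE 0.22). Copies elsewhere shared 43.1% of U2af2's sequence. The first, noncoding exon of Hsp90ab1, a heat shock protein (chromosome 17, 45573167 to 45573253; 1.60, SE 0.13), and a coding exon of Mcm10, a DNA replication factor (chromosome 2, 5008480 to 5008812; 2.20, SE 0.19), were used more. These segments differed between groups while the whole-gene log2 fold changes of Synj2bp (0.23), Kazn (-0.29), U2af2 (-0.29) and Hsp90ab1 (-0.22) did not pass, while that of Mcm10, which fell, was -1.02.

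In all, 1212 of 108630 exon segments passed in limma's diffSplice, 450 used more and 762 used less in iTDPKO, in 955 of 10481 genes. Genes with such a segment were abundant, with a median of 150 CPM against 39.1 CPM over all genes tested. The count was 53 without cTDP replicate 1, 454 without cTDP replicate 2 and 487 without iTDPKO replicate 2. With reads of 1 start and strand counted once only 28 segments passed, 27 of them among the 1212. That count is limited by the number of start positions in a segment, so short, abundant segments lose reads and differences by construction. The segments of Synj2bp, Kazn and Mcm10 passed in that alternative, and those of Hsp90ab1 (0.46) and U2af2 (-0.50) missed the threshold. The Hsp90ab1 segment has 87 bases, with 4815, 4593 and 1498 reads in iTDPKO and 1324 and 270 in cTDP. Its smaller value there cannot decide whether its use changed.

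Introns of some genes carried reads in iTDPKO that were nearly absent in cTDP. In an intron of Synj2bp (mm9, chromosome 12, 82610800 to 82610999), 124, 134 and 43 reads lay in the iTDPKO libraries and 2 and 0 in the cTDP libraries. The log2 difference from the gene's exonic reads and other tested intronic segments was 5.18 (SE 0.70, limma adjusted p 7.4e-05). In Glis2, a zinc finger transcription factor (chromosome 16, 4612000 to 4612199), there were 70, 46 and 27 reads against 4 and 2 (3.53, SE 0.55), and in Glb1, the lysosomal beta-galactosidase (chromosome 9, 114375200 to 114375399), 30, 18 and 19 against 3 and 2 (3.10, SE 0.55). The contrast was smaller in Rfc2 (chromosome 5, 135067800 to 135067999), with 16, 18 and 5 against 7 and 1 (3.13, SE 0.53), or means of 1.54 and 0.634 CPM. Cdyl, a chromodomain corepressor (chromosome 13, 35945400 to 35945599), went the other way, with 20, 11 and 9 against 69 and 17 (-2.17, SE 0.36). Hmgxb3, an HMG-box gene chosen after its values were seen, had 68, 65 and 24 reads in 1 segment against 0 and 0 (chromosome 18, 61320000 to 61320199), at least 24.0-fold higher in CPM when cTDP is set to 3 counts over the group.

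Of 9075 intronic segments of 200 bases in 2874 genes, 53 passed in limma's diffSplice, 51 higher and 2 lower, and 507 higher and 472 lower had an unadjusted p under 0.05. The split was 68 higher and 11 lower with the read minimum doubled, 82 and 11 with 500-base segments and 54 and 9 with the narrow span. It was 16 and 0 with reads of 1 start and strand counted once and 14 and 2 with the replicate block. The 51 higher segments lay in 30 genes, of which 14 fell in the gene test and 0 rose. Of the 2842 genes with tested segments but none that passed, 96 fell. The value is relative to the gene's exonic reads and its other tested intronic segments. A gene that falls, as Rfc2 and Glb1 (-2.07) did, can therefore raise it with no added intronic read. In 46 of the 51 higher segments every iTDPKO library also lay above both cTDP libraries in CPM. Without cTDP replicate 1 no segment passed, with 18 higher and 375 lower at an unadjusted p under 0.05, and the adjusted p of the 5 leading genes lay between 0.215 and 0.638. Their log2 differences there were 5.34 for Synj2bp, 3.51 for Rfc2 and -2.49 for Cdyl, no smaller than with all libraries, and 2.06 for Glb1 and 2.24 for Glis2, which were smaller. Cdyl had -1.40 (adjusted p 0.260) with reads of 1 start and strand counted once. The count was 7 without cTDP replicate 2, 32 without iTDPKO replicate 3, and 5 without both libraries with many uncalled bases, where Synj2bp and Glb1 had adjusted p of 0.338 and 0.343 at log2 differences of 5.28 and 3.14.

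**Figure D4:**
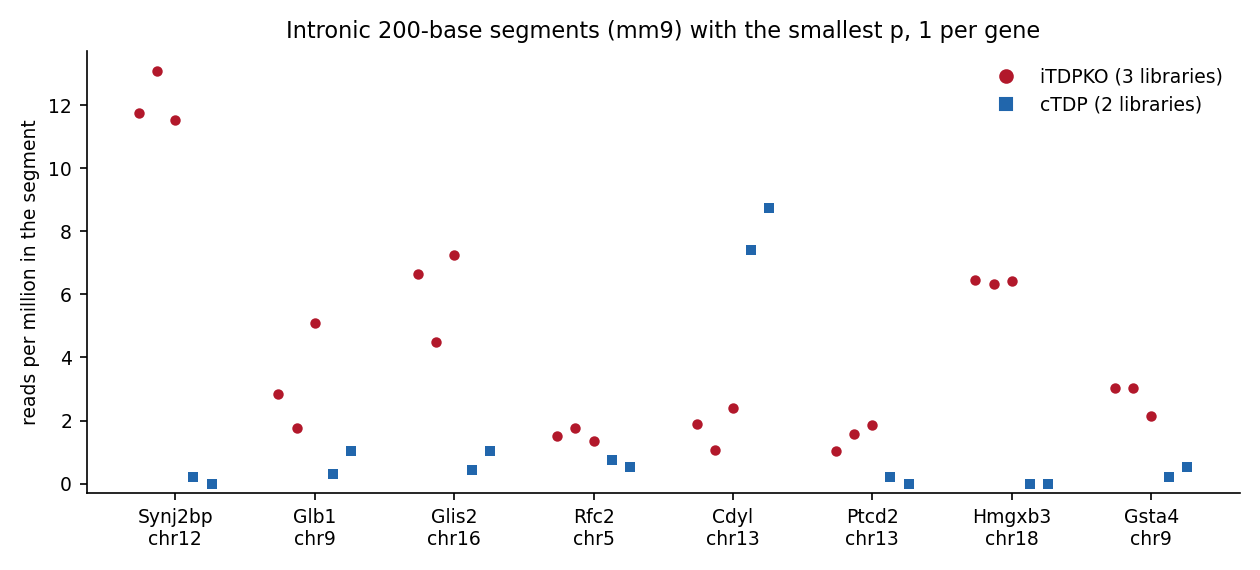
CPM (vertical axis) in the intronic segment with the smallest adjusted p of each of 8 genes (horizontal axis), in every library (points). The Synj2bp segment had 124, 134 and 43 reads in iTDPKO and 2 and 0 in cTDP.

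Change in expression had no steady relation to intron length across genes, though genes that passed as lower were most frequent in the class with the longest introns. Earlier work on nervous tissue tied loss of TDP-43 to genes with long introns, and here Spearman's rho between a gene's log2 fold change and its total intron length was -0.0089 across 12632 genes, which are not independent replicates. Within 5 bins of expression rho lay between -0.0080 and 0.0041. Between libraries of 1 group the same correlation ran from -0.153 to 0.0520, so the value lay within the spread of replicates. It became -0.0922 without cTDP replicate 1 and 0.0364 without cTDP replicate 2, and so had no stable sign. The medians of the 10 length classes lay between -0.01 and 0.02, the lowest in the longest class. In the longest class 46 of 1264 genes fell and 4 rose, and in the shortest 23 of 1264 fell and 10 rose, a difference that was not tested.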

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

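The junction-only, chromosome 6, span and uncalled-base alternatives were chosen after the data were seen. Tardbp and Tbc1d1 passed in each alternative run, with log2 fold changes of -1.98 to -2.71 and -2.54 to -3.01. Against the 357 genes that passed, the number was 340 to 380 with median-of-ratios or total-count scaling, with either filter or with the GC correction (292 to 357 of the same genes), 323 with limma-trend, 516 with sample quality weights, 264 at a score of at least 100 (257 of the same genes), 276 on junction reads alone (129) and 377 without chromosome 6. The count was 187 with libraries thinned to the shallowest, 72 with reads of 1 start and strand counted once and 211 without both libraries with many uncalled bases (iTDPKO replicate 3 and cTDP replicate 2). Leaving out each library in turn gave 30 to 368. The share of higher genes, 20.2%, became 8.33% with repeated starts counted once, 0% without cTDP replicate 1 and 9.43% without cTDP replicate 2. With no filter the median log2 fold change of all genes moved from 0.00 to -0.11. Thinning and leaving out libraries lower the depth or the number of samples by construction. Counting repeated starts once limits the reads that short or abundant genes and segments can hold, also by construction. How much of each change comes from this was not tested, nor was the cause for the other alternatives.

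The number of lists that passed, 2, became 8 with no filter, 1 with the GC correction, 1 when thinned, 4 without both libraries with many uncalled bases, and 0 to 5 with each library left out in turn. The 1212 exon segments became 28 with repeated starts counted once, of which 27 had passed before, 1779 with the read minimum doubled, 995 with the default span, 882 without both libraries with many uncalled bases, and 53 to 1589 with each library left out. The 53 intronic segments became 16 with repeated starts counted once, 79 with the read minimum doubled, 93 with 500-base segments, 63 with the narrow span, 5 without both libraries with many uncalled bases and 0 to 46 with each library left out. Apart from the limits by construction given above, the cause was not tested. Of the 39 other named genes 1 reversed, Eno1, at -0.17 with repeated starts counted once. In that alternative 25 missed the threshold, Eno1 included, as did 31 without cTDP replicate 1, 24 without cTDP replicate 2, 9, 8 and 3 without iTDPKO replicates 1, 2 and 3, 16 of 34 on junction reads, 14 without both libraries with many uncalled bases, 11 when thinned and 0 to 6 in each of the rest.

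The groups share replicate numbers 1 and 2 but nothing pairs them: deviations of same-numbered libraries correlated at -0.056 and -0.213. With the number as a replicate block 588 genes (333 of the 357 among them), 8 lists (TDP-43 targets, cryptic exons, body weight, hnRNP, chaperones and interferon response besides the 2), 751 exon segments and 16 intronic segments passed, and 618 genes, 33.3% of them higher, passed with the block and the GC correction together. The block adds terms to a fit of few libraries, so little is left to measure their spread. As the only library in its block, iTDPKO replicate 3 adds nothing to the difference between groups. Beyond these limits, the cause was not tested. Cutting reads to 1 length was not run, since all reads have 40 bases. Where leaving out a library leaves 1 cTDP library, it is assumed to vary like the iTDPKO libraries. Thinning kept 170 of the 353 genes still tested. With simulated changes at the real depths, 56.1% of 1.5-fold genes and 38% of 4-fold intronic segments were called, where depth and the number of libraries limit together and were not varied apart.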

Other observations

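The test of the host genes of intronic segments, and the narrow-span version of the test of GU repeats, were chosen after the result was seen. The predictions for the other tests were written before the values they measure. A difference between the ES cell lines that is unrelated to the deletion was not tested and stays open for each pattern.

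The segments of this paragraph were chosen after their values were seen. In Smarca4, the ATPase of the BAF chromatin remodelling complex, an exon segment (GRCm38, chromosome 9, 21703367 to 21704217) had 288, 283 and 86 reads in the iTDPKO libraries and 14 and 1 in the cTDP libraries, with a log2 difference in use of 4.44 (SE 0.52), while the whole gene had -0.16. In Apoe, the apolipoprotein, a junction (mm9, chromosome 7, 20282453 to 20282827) was used less (log2 -1.86, SE 0.20), and a segment of 60 bases (GRCm38, chromosome 7, 19698188 to 19698247) more (1.94, SE 0.23). The iTDPKO libraries had 894, 914 and 340 reads on that junction and the cTDP libraries 1347 and 253.

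Intronic reads that appeared in iTDPKO may come from exons that TDP-43 keeps out of mRNA, a candidate explanation from its known role. A library-wide excess of unspliced RNA or genomic DNA is argued against: the 9022 segments that did not pass had a median log2 ratio of -0.024. The higher segments had 3.19, which is high by their selection and is no contrast. A median over many genes does not address unspliced RNA of particular genes. A run of 8 alternating G and U bases, a repeat of the kind that TDP-43 binds, was found on the gene's strand near the segments of 23.3% of the 30 genes, against a median of 13.3% in matched segments (permutation p 0.0709), and of 28.2% of 39 genes with the narrow span (p 0.0071), so the repeat stays open; on the other strand the shares were 20% (p 0.0242) and 15.4% (p 0.0836). Host genes had a median log2 fold change of -0.43, against -0.015 for matched genes (permutation p 1e-04, the smallest that 10000 draws give), and 25 of 30 were lower. This is open too, because the test is relative in part to the gene's exonic reads. A gene that falls for another reason can thus raise its intronic values.

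Differences in exon use may reflect splicing or a shift in where reads start. Genes with an exon segment that passed held a junction that passed in 41.3% of 870 cases, against 29.5% of genes with as many junction reads (permutation p 1e-04, the smallest that 10000 draws give), over 1563 junctions that passed of 44251. Junction reads were also counted in the exon segments. The 2 tests thus share reads and libraries, and this excess is not independent support for splicing. In 389 abundant genes with no such segment, the read-start profiles of libraries from different groups differed 1.03 times as much as those from 1 group, between the bounds set beforehand, and the ratio was above 1 in 85.3% of these genes. The 211 abundant genes with such a segment had 1.05 and 90.5%. A shift of starts would also move junction reads, so the 2 explanations cannot be told apart for these genes.

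The higher RNA of chromosome 6 in iTDPKO replicate 2 may come from an extra chromosome 6 in part of that culture's cells. Split in map order into 3 parts, the chromosome's genes had median log2 differences between 0.29 and 0.31, and 23.4% more RNA compares with 50% more if every cell had 3 copies. A few strongly changed genes are argued against by the median itself, which a few among 411 genes could not move to 0.30. The share of genes highest in that library exceeded that of other chromosomes by 44.5 percentage points (67.9% against 23.4%). That excess largely follows from the median and adds little as a test. GC content is argued against too, with a median of 0.31 after correction and 0.30 before. No DNA was analysed here, and of the 357 genes that passed 12 lie on chromosome 6, 6 higher and 6 lower.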
